A study of Mus musculus with 12 samples.

How the data were processed

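Total RNA (100 ng per sample, RNeasy columns with DNase I) was labelled as biotinylated cDNA and hybridized to Affymetrix Mouse Gene 2.0 ST arrays. The 12 arrays came from iTSC clone 3.8, iTSC clone 6.6, ES cell line D3 and hepatocytes, with 3 arrays each. Per the series description, adherent liver cultures from mice aged 6 to 8 weeks were infected with adenovirus carrying Oct4, Sox2, cMyc and Klf4, pooled after 5 days and plated on arrested embryonic fibroblasts in ES cell medium. The clones 3.8 and 6.6 were grown from single cells of separate colonies. The origin of the replicates and the sex of the animals are not given in the sources used here.

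The deposited values are log2 intensities that the authors made by robust multi-array average (RMA), which corrects background, normalizes quantiles between arrays and summarizes probes per feature. Partek and R Bioconductor were used by the authors for annotation. Their versions and the genome build are not given in the sources used here, so no positions are reported. The value range, the array medians and the column quantiles were checked and fit a log2 scale. Values were used as deposited, without further normalization or pseudocount.

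The table held 35960 features. A platform annotation gave exactly 1 gene symbol for 23521, several for 1814 and none for 10625 of them. Of the former, 23328 had an Entrez identifier in the reference table, and 0 symbols needed an update. Features with several symbols or none were not named. For the 1082 genes with more than 1 feature the brightest was used, which left 22180 genes. No detection calls were used. As a level for genes without expected signal, the median and the 95th percentile of olfactory and vomeronasal receptor genes were taken, a choice made after seeing the data. The number of arrays limits the precision.

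Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 12 arrays, with 1 coefficient per group, for 8 comparisons. These were ES cells against hepatocytes, the mean of both clones against hepatocytes and against ES cells, clone 6.6 against clone 3.8, and each clone against each reference. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison and an absolute log2 difference of at least 1 (2-fold). SE is the moderated standard error of limma for single genes. For means over several genes it was computed from the SDs of the arrays within groups, without moderation.

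The 36 gene lists were fixed before the data were examined. They covered introduced factors, naive and primed pluripotency, plasma proteins, urea cycle, drug metabolism, gluconeogenesis, liver transcription factors, hepatoblast, cholangiocyte, fibroblast, stellate cell, Kupffer cell, lymphocyte, sinusoidal endothelium, erythroid, epithelial, mesenchymal transition, mesenchymal stem cell, tissue stem cell, cell cycle, p53, endoderm, mesoderm, neuroectoderm, trophoblast, germ cell, imprinted, DNA methylation and Polycomb, glycolysis, oxidative phosphorylation, interferon, immediate early, acute phase, sex-linked and widely expressed reference genes. Lists share some members. Each list was tested with camera in limma (preset correlation 0.01) in 4 comparisons, with Benjamini-Hochberg adjustment over the 144 tests, and again with a correlation estimated per list and with fry. An adjusted p in the text that stands alone in parentheses after a list is that of camera, and one after "without" or "after" is that of camera under the setting named.

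Named genes were chosen by a rule fixed in advance. For each of the 4 comparisons with list tests it took the 10 called genes with the largest rise and the 10 with the largest fall whose arrays did not overlap, leaving out predicted, RIKEN, small RNA, receptor and immunoglobulin symbols. Chance gives no overlap in 10% of genes for 3 against 3 arrays. It added the introduced factors and up to 4 called members per list. Correlations between arrays were Pearson r across genes. List positions and the correlation of clone arrays with each reference were compared by exact permutation or sign-flip tests, two-sided.

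The procedure was tested on simulated data with the spread of these arrays. Of 40 genes changed by a log2 difference of 1.5, between 95% and 100% were called in each comparison, and of those changed by 1, between 40% and 67.5%. At most 2 of the unchanged genes were called. Of 100 unchanged lists 1 gave a camera p under 0.05. The simulated genes varied independently of each other, so this cannot test camera on lists whose genes move together.

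Alternatives fixed in advance were repeated quantile normalization, centring on array medians or on the reference genes, leaving out dim features, all features, the mean of a gene's features, no minimum difference, a minimum of 2, treat, array weights, trended and robust variance priors, fits of only the groups compared, replicate number as a block, leaving out each array, Spearman correlation and medians over list members. List counts without clone 6.6 replicate 1, without hepatocyte replicate 1 and without ES cell replicate 3 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.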

Results

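Gene expression was measured on 12 Affymetrix Mouse Gene 2.0 ST arrays from 4 groups of 3 replicates. The groups were induced tissue stem cell (iTSC) clone 3.8, iTSC clone 6.6, the mouse embryonic stem (ES) cell line D3, and C57BL/6 hepatocytes. The iTSC clones descend from liver cultures that received Oct4 (Pou5f1), Sox2, cMyc (Myc) and Klf4 by adenovirus. Array medians lay between 4.63 and 4.85 on the log2 scale over all 35960 features, of which 22180 represented the named genes compared. The 1390 olfactory and vomeronasal receptor genes, for which little signal is expected in these cells, had a median of 2.89 and a 95th percentile of 5.01. Between 10622 and 10958 genes per array lay above that percentile. A fold against a level in this receptor range is compressed. The number of arrays limits the precision. Whether replicates were separate cultures, passages or RNA preparations is not given in the sources used here, so each p measures the spread between samples of a group. For the mean of both clones, n = 6 counts 3 arrays of each of 2 clones. The spread between the clones does not enter those SE and p values, which therefore do not extend to further clones.

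The clones resembled each other more than either reference cell type. Across genes, the mean Pearson r was 0.963 between clone 3.8 and clone 6.6 arrays (9 pairs), against 0.99, 0.984, 0.99 and 0.984 within clone 3.8, clone 6.6, ES cells and hepatocytes. The 6 clone arrays correlated with the ES cell mean at 0.887 (SD 0.00955) and with the hepatocyte mean at 0.813 (SD 0.00705). The difference had the same sign on 6 of 6 arrays and averaged 0.0735 (SD 0.0155), with an exact two-sided sign-flip p = 0.0312, the smallest that 6 arrays allow. This test takes arrays as units that vary independently, although 3 come from each clone, and the 2 clones as units could not reach it. The size of the difference depended on the measure, with 0.902 for ES cells and 0.865 for hepatocytes by Spearman and 0.758 and 0.596 without dim features. ES cells and hepatocytes correlated at 0.771. Genes are not independent replicates, so these r values describe profiles and carry no error over genes.

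Some arrays stood apart within their groups. Clone 6.6 replicate 1 had a median of 4.85 and an SD of 2.05, correlated with another array of its clone at 0.978, the lowest value in that group, and received an array weight of 0.271 where the other arrays received 0.627 to 3.77. Hepatocyte replicate 1 had higher values of genes that were high in the clones. Of 46 genes at least 3 log2 units higher in both clones than in both references, 43 were highest in their group on this array (93.5%, where chance gives 33.3%), by a median of 0.96 over the other hepatocyte arrays. Xist measured 7.56 on hepatocyte replicate 1 and 5.82 and 5.86 on the other hepatocyte arrays, and Bicc1 measured 7.18 against 5.26 and 5.66. ES cell D3 replicate 3 showed a smaller shift, with 29 of the 46 genes highest (63%) and Apob at 6.59 against 4.13 and 4.24. These genes and thresholds were chosen after per-array values of 12 plotted genes had been seen, and those 12 were left out of the 46.

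**Figure D1:**
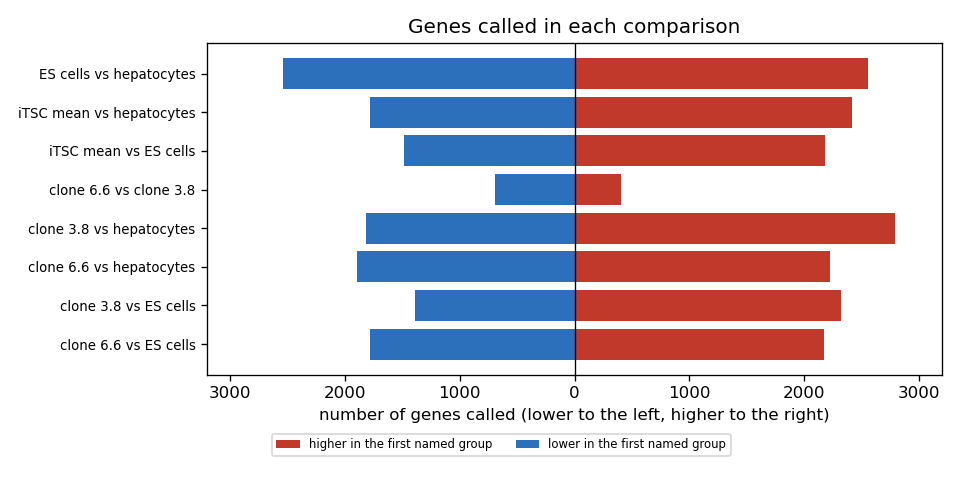
The bars give the number of genes called higher (right) and lower (left) in the first-named group of each of 8 comparisons, out of 22180 genes tested. The ES cell against hepatocyte bars hold 2558 and 2539 genes, and the clone 6.6 against clone 3.8 bars hold 402 and 691.

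The comparison of ES cells with hepatocytes asked how the reference cell types differ. ES cells expressed the pluripotency network and hepatocytes the secretory and metabolic programme of liver. Tdgf1, a Nodal co-receptor of early embryo cells, was higher in ES cells by 7.23 log2 units (SE 0.35, n = 3 and 3 arrays, limma adjusted p = 6.03e-11), a 150-fold difference. Nanog, a core pluripotency factor, was higher by 6.02 (SE 0.21). Fgg, the fibrinogen gamma chain, fell by 9.28 (SE 0.13, adjusted p = 2.4e-16), a 620-fold difference, and Hamp, which encodes hepcidin, fell by 9.39 (SE 0.30). Of 22180 genes, 2558 were called higher in ES cells and 2539 lower.

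By list, all 32 measured naive pluripotency genes were higher in ES cells (camera adjusted p = 4.88e-25), including Fbxo15 at 6.60 and Sox2 at 6.48. Of 14 primed pluripotency genes, 4 were higher, among them Dnmt3b at 3.26 and Lefty2 at 2.40 (camera adjusted p = 0.0118, adjusted p = 0.101 with an estimated correlation). All 39 plasma protein genes were lower (8.44e-40), as were 26 of 29 genes of the urea cycle and amino acid catabolism (7.35e-24), 31 of 32 of drug metabolism and bile acids (4.7e-31), 20 of 21 of gluconeogenesis and lipid metabolism (9.45e-18) and 20 of 21 liver transcription factors (9.54e-15). Examples were Tdo2, a tryptophan-degrading enzyme, at -7.84, Otc of the urea cycle at -6.96, the bile acid transporter gene Slco1b2 at -8.28, Pck1 of gluconeogenesis at -6.85 and the bile acid receptor gene Nr1h4 at -5.63. These liver lists and the naive list also passed with an estimated correlation.

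Proliferation and chromatin genes were higher in ES cells. The cell cycle list had 36 of 37 members higher, including the mitotic checkpoint gene Bub1 at 5.04 (camera adjusted p = 7.17e-24, adjusted p = 0.176 with an estimated correlation). The DNA methylation and Polycomb list had 16 of 19 higher, with the demethylation enzyme gene Tet1 at 5.79 (4.6e-11), and it passed with an estimated correlation. Germ cell genes were higher in 13 of 19 cases, such as Stra8 at 3.25 (camera adjusted p = 3.08e-06, adjusted p = 0.0561 with an estimated correlation). Imprinted genes were higher in 9 and lower in 1 of 26, with Peg10 at 3.70 (camera adjusted p = 0.000813, adjusted p = 0.13 with an estimated correlation). Glycolysis genes were higher in 10 and lower in 2 of 19, with Pkm at 4.14 (camera adjusted p = 0.000114, adjusted p = 0.256 with an estimated correlation). Of the introduced factors, Sox2, Klf4 (3.39) and Pou5f1 (1.70) were higher and Myc was not called (-0.12, SE 0.18). That list of 4 passed camera (adjusted p = 0.0135) but not with an estimated correlation (adjusted p = 0.198 with an estimated correlation) nor with dim features left out (adjusted p = 0.0514).

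Other cell types' markers were also measured, and several were higher in the hepatocyte arrays. The sinusoidal endothelium list had 9 of 22 members lower and 1 higher in ES cells, with the endothelial lectin gene Clec4g at -3.10 (camera adjusted p = 0.00111, passing with an estimated correlation). The Kupffer cell and macrophage list had 6 of 23 lower and 2 higher, with the lysozyme gene Lyz2 at -2.87 (camera adjusted p = 0.0139, adjusted p = 0.197 with an estimated correlation), and it missed the threshold with arrays centred on reference genes (0.0518) and with dim features left out (0.191). Interferon response genes were lower in 16 of 25 cases, with Ifi27 at -5.49 (1.36e-07), and acute phase genes in 13 of 17, with Saa2 at -7.33 (2.21e-10). Both of these passed with an estimated correlation. Of the immediate early and dissociation stress list, 12 of 20 were lower and 4 higher, with Jun at -4.99 (camera adjusted p = 0.0139, adjusted p = 0.401 with an estimated correlation, and 0.0725 after centring on reference genes). The hepatoblast list had 7 higher and 2 lower of 16, or 1 lower without hepatocyte replicate 1, with Epcam at 4.36 (camera adjusted p = 0.0265, adjusted p = 0.11 with an estimated correlation, and 0.0755 without dim features). Oxidative phosphorylation passed as lower relative to other genes (camera adjusted p = 0.00691, adjusted p = 0.558 with an estimated correlation) with 1 of 30 members called higher and 1 lower (2 lower without hepatocyte replicate 1 and 0 without ES cell replicate 3).

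The other 16 of 36 lists did not pass in this comparison, and the mean, median and test differed in sign for the fibroblast, lymphocyte, erythroid and trophoblast lists. Without hepatocyte replicate 1 the tissue stem cell list passed (adjusted p = 0.0308), as it did after centring on reference genes (0.0266). Counts adjusted over the list alone equalled those over all genes for every list in this and the other comparisons. Centring arrays on the 12 widely expressed reference genes moved the median difference of all genes from -0.02 to -0.325 and the share of calls that were higher from 50.2% to 34.6%, and centring on array medians moved that median to -0.101.

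**Figure D2:**
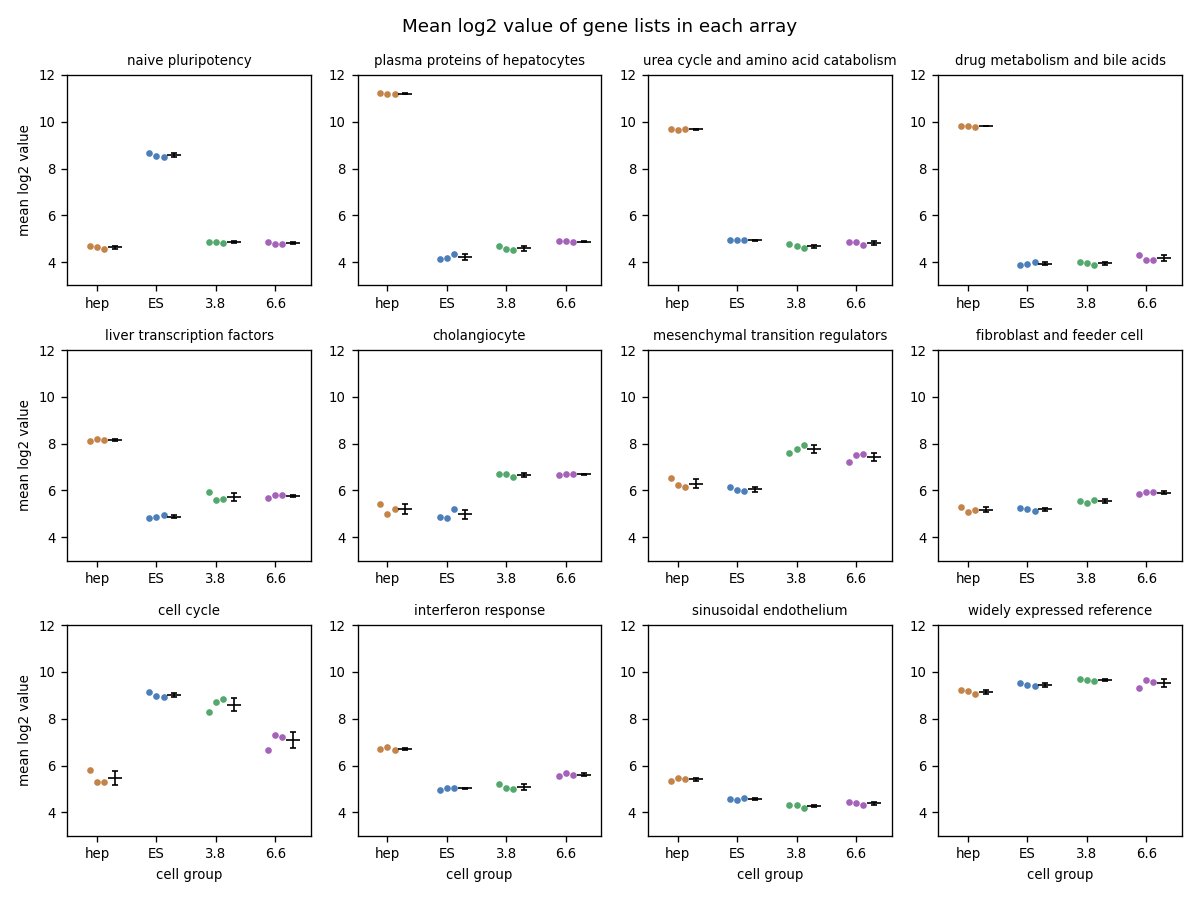
Each panel gives the mean log2 value over the members of 1 gene list for each of the 12 arrays (points), with the group mean and SD (dash and bar). Naive pluripotency lay at 8.58 in ES cells and at 4.86, 4.80 and 4.64 in clone 3.8, clone 6.6 and hepatocytes, whereas plasma proteins lay at 11.21 in hepatocytes and at 4.58, 4.88 and 4.22 in clone 3.8, clone 6.6 and ES cells.

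The comparison of the iTSC clones with hepatocytes asked how the clones differed from hepatocytes, the cell type that the series title names as their source. Genes of the hepatocyte programme were far lower in the clones. Fgg fell by 9.42 log2 units (SE 0.11, n = 6 and 3 arrays, limma adjusted p = 2.13e-17), a 686-fold difference, from 12.07 in hepatocytes to 2.59 in clone 3.8 and 2.71 in clone 6.6, which is within the receptor range. Fabp1, the liver fatty acid binding protein, fell by 9.47 (SE 0.12). The largest rises among the genes taken by the fixed rule were in Ccl2, a monocyte chemokine, at 5.54 (SE 0.46, adjusted p = 4.87e-08, and 6.13 without hepatocyte replicate 1), the transcription factor gene Sox4 at 5.22 (SE 0.27) and Cpe, carboxypeptidase E, at 5.17 (SE 0.24). Bicc1, an RNA-binding protein of bile duct and kidney epithelium, rose by 5.00 (SE 0.36), a 32-fold difference. In total 2414 genes were higher and 1787 lower. The SE and p values here leave out the spread between the clones.

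Of 39 plasma protein genes 37 were lower in the clones and none higher (camera adjusted p = 2.51e-40), including Ambp at -8.81 and Ahsg, fetuin-A, at -8.46. The urea cycle and amino acid catabolism list had 27 of 29 lower (1.61e-28), with Cps1, the enzyme that starts the urea cycle, at -7.25. The drug metabolism and bile acid list had 31 of 32 lower (4.07e-33), with Slco1b2 at -8.47 and Cyp2e1 at -7.69. Gluconeogenesis and lipid metabolism genes were lower in 20 of 21 cases (1.33e-20), with Pck1 at -6.85 and Fbp1 at -7.41. Liver transcription factors were lower in 16 of 21 (4.46e-10), with Nr0b2 at -5.81, the xenobiotic receptor gene Nr1i2 at -4.62 and Cebpa at -4.43. Acute phase genes were lower in 11 and higher in 2 of 17 (1.07e-06), with Fgl1 at -7.55 and Cd14, a lipopolysaccharide co-receptor, at 3.71. Interferon response genes were lower in 14 of 25 (1.36e-07), with Isg15 at -2.70. All of these lists passed with an estimated correlation. Several families here (Serpina1, Mup, Ugt2b, Cyp2d) hold close paralogs whose probes may be shared, so their members are not separate evidence.

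The clones did not show the ES cell pluripotency network. Of 32 naive pluripotency genes 4 were higher than in hepatocytes and none lower (camera adjusted p = 0.945), and of 14 primed genes 1 was higher (0.829). The naive genes named were Klf5 at 3.77, Tfcp2l1 at 1.87 and Klf4 at 1.81. Nanog measured 4.44 in clone 3.8, 4.63 in clone 6.6, 4.55 in hepatocytes and 10.57 in ES cells. Among the introduced factors, Klf4 and Myc (1.21, SE 0.16) were higher. The Myc call ended with arrays centred on reference genes (0.78). Pou5f1 differed by 0.13 (SE 0.13, adjusted p = 0.44) and Sox2 by 0.93 (SE 0.22), under the minimum difference. The Pou5f1 feature read only 6.12 to 6.54 in ES cells. In clones and hepatocytes it read 4.32 to 4.79, under the receptor 95th percentile of 5.01. With so small a response in ES cells it cannot show whether the clones lacked Pou5f1. Sox2 lay at 6.73 in clone 3.8, 3.34 in clone 6.6 and 4.10 in hepatocytes, and without hepatocyte replicate 1 its mean difference was 1.21 and it was called, as it was without clone 3.8 replicate 3 (1.00) or clone 6.6 replicate 2 (1.03). The list of 4 did not pass (adjusted p = 0.0758, and 0.0395 after centring on reference genes). Endogenous and introduced transcripts were not told apart here.

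Cell cycle genes rose in the clones, with 34 of 37 higher and none lower (camera adjusted p = 1.44e-19, adjusted p = 0.224 with an estimated correlation). Kif11, a mitotic motor, was higher by 3.55 (SE 0.22) and Mki67, a proliferation marker, by 3.45 (SE 0.24). The list mean was 8.61 in clone 3.8, 7.07 in clone 6.6 and 5.47 in hepatocytes, with hepatocyte replicate 1 at 5.82 and the others at 5.31 and 5.29. The p53 and senescence list had 8 higher and 2 lower of 15, with the cell cycle inhibitor genes Cdkn1a at 3.23 and Cdkn1b at 1.86 higher and Btg2 at -1.98 (camera adjusted p = 0.0461, adjusted p = 0.456 with an estimated correlation). That call was lost without clone 3.8 replicate 1 (0.0707) or clone 6.6 replicate 3 (0.0513), after renormalization by quantiles (0.0752) and without dim features (0.191). The DNA methylation and Polycomb list had 6 of 19 higher, with Ezh2 at 2.87 (camera adjusted p = 0.0144, adjusted p = 0.269 with an estimated correlation, and 0.134 without dim features). Oxidative phosphorylation had 3 of 30 lower and none higher (2 lower in clone 3.8 and 9 in clone 6.6), with Sdhb at -1.82 (camera adjusted p = 1.34e-06, adjusted p = 0.311 with an estimated correlation).

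Parts of the cholangiocyte and mesenchymal lists were higher in the clones. Of 14 cholangiocyte genes 7 were higher and 1 lower, with the annexin gene Anxa13 at 4.46 and the duct keratin gene Krt19 at 3.27 beside Bicc1 (camera adjusted p = 0.00737, adjusted p = 0.0895 with an estimated correlation). Of 21 mesenchymal transition regulators 9 were higher and 1 lower (camera adjusted p = 6.95e-05, adjusted p = 0.282 with an estimated correlation). The receptor kinase gene Axl was at 3.96 (SE 0.20), the matricellular gene Ccn2 at 3.72 (SE 0.25), which has a second feature at 1.02, and the intermediate filament gene Vim at 3.71 (SE 0.23). Tgfbi was at -1.33. Mesenchymal stem cell surface markers were higher in 7 and lower in 1 of 17, with Cd44 at 4.19, Vcam1 at 2.96 and Eng at -1.57 (camera adjusted p = 0.00986, adjusted p = 0.247 with an estimated correlation, and 0.0655 without dim features). Hepatocyte replicate 1 also had the highest values of its group for these lists, at 5.42 against 4.99 and 5.22 for the cholangiocyte list and at 6.51 against 6.23 and 6.13 for the mesenchymal list.

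Fibroblast and feeder cell markers did not pass as a list (0.244), with 7 of 30 higher, such as S100a4 at 4.41, Fbln2 at 3.90 and Col12a1 at 3.80, and 2 lower. Sinusoidal endothelium markers were lower in 10 and higher in 1 of 22, with Clec4g at -3.63 (1.26e-06, passing with an estimated correlation), and Kupffer cell and macrophage markers were lower in 7 and higher in 2 of 23, with Lyz2 at -2.87 (camera adjusted p = 0.00198, adjusted p = 0.109 with an estimated correlation, and 0.0655 without dim features). Hepatic stellate cell markers gave 2 higher and 3 lower of 18 (0.728), and the mean, median and test differed in sign for this list and for trophoblast. Hepatoblast and liver progenitor genes gave 7 higher and 1 lower of 16 (0.0605), with Cd24a at 4.05 (4.83 without hepatocyte replicate 1) and Tnfrsf12a at 3.11. The lower member was Afp, whose call ended without hepatocyte replicate 1 (-0.88). Afp lay under the receptor 95th percentile on every clone and hepatocyte array except that one (5.06). Epcam and Gpc3 lay under that percentile on all clone and hepatocyte arrays. That list passed without hepatocyte replicate 1 (0.0336) or clone 6.6 replicate 3 (0.0494), after renormalization by quantiles (0.0466) and after centring on reference genes (0.0127).

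The remaining lists did not pass. Higher and lower counts were 6 and 2 of 19 tissue stem cell markers (0.159), 2 and 7 of 26 epithelial junction and keratin genes (0.31), 7 and 1 of 22 endoderm genes (0.149), 1 and 1 of 18 mesoderm genes (0.422) and 1 and 0 of 21 neuroectoderm genes (0.587). They were 1 and 0 of 16 trophoblast genes (0.713), 6 and 1 of 26 imprinted genes (0.31), 8 and 3 of 19 glycolysis genes (0.127), 4 and 9 of 20 immediate early genes (0.236) and 3 and 0 of 12 reference genes (0.101). No member was called among 19 germ cell (0.79), 19 lymphocyte and neutrophil (0.332) and 5 erythroid genes (0.55). The erythroid gene Klf1 was called lower without hepatocyte replicate 1 (-1.09) or with arrays centred on reference genes (-1.33). After centring on reference genes the tissue stem cell (0.0442) and glycolysis (0.0422) lists passed, the latter with its mean turned to -0.02.

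Sex-linked genes separated the clones from the hepatocytes. Xist, the RNA that coats the inactive X chromosome, rose by 5.08 (SE 0.32, adjusted p = 1.74e-09) and lay between 11.18 and 11.79 on the 6 clone arrays. The Y-linked genes Eif2s3y, Uty and Kdm5d fell by 4.85, 3.06 and 3.02. The list of 6, which holds genes of both chromosomes, gave 1 higher and 3 lower and did not pass (0.174).

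Of 36 lists, 16 passed camera in this comparison, 8 with an estimated correlation and 29 by fry, which tests whether a set moves on balance in 1 direction. Centring on reference genes moved the median difference of all genes from -0.037 to -0.473 and the share of calls that were higher from 57.5% to 31.4%.

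**Figure D3:**
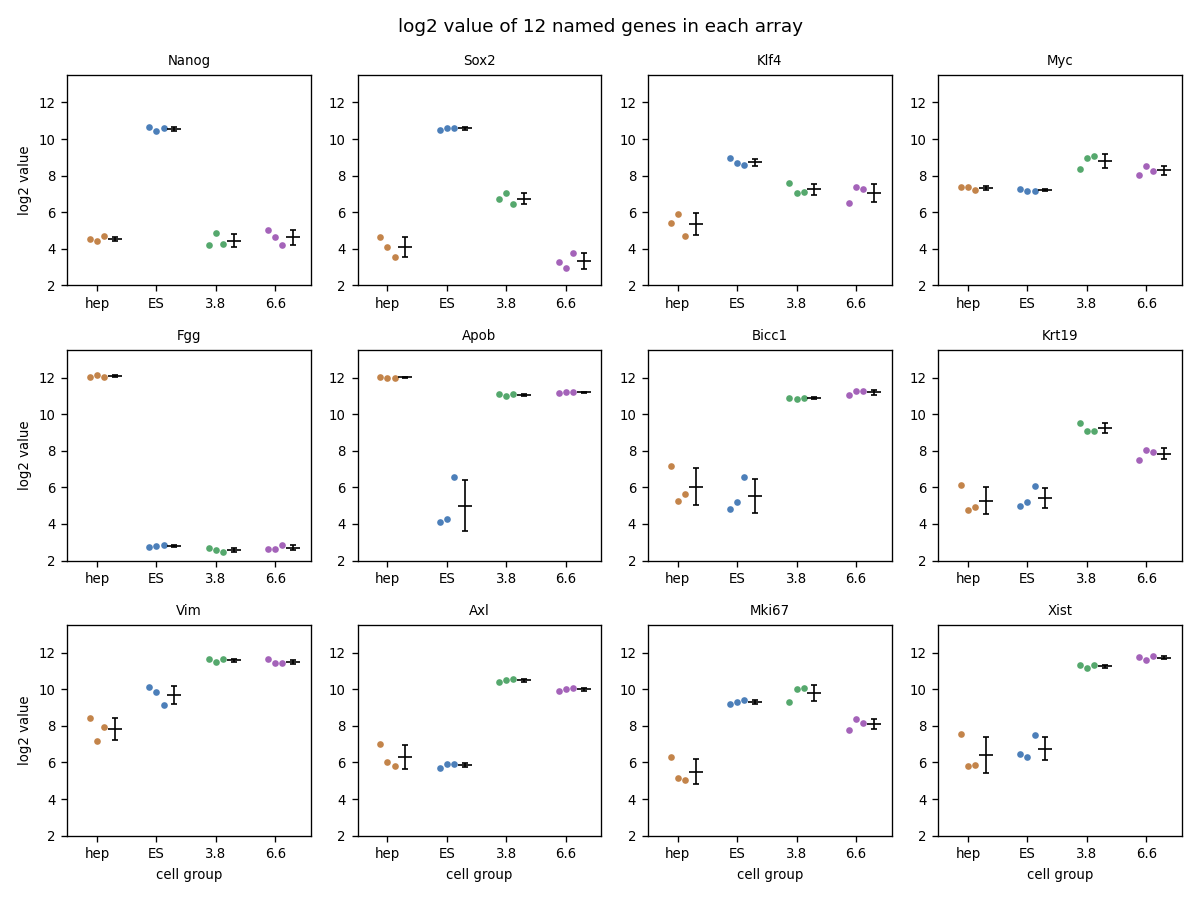
The log2 values of 12 genes are shown on each of the 12 arrays (points), with group means and SD (dash and bar). Fgg lay at 12.07 in hepatocytes and between 2.59 and 2.79 in the other groups, Nanog at 10.57 in ES cells, and Xist between 11.18 and 11.79 on clone arrays.

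The comparison of the clones with ES cells asked how close the clones came to pluripotent cells. Naive pluripotency genes were far lower in the clones, and Tm4sf4 and Apob were among the genes with the largest rises. Tdgf1 fell by 7.67 log2 units (SE 0.30, n = 6 and 3 arrays, limma adjusted p = 1.85e-11), a 204-fold difference, and Nanog fell by 6.03 (SE 0.18, adjusted p = 1.12e-12). Tm4sf4, a tetraspanin-like membrane protein of liver, was higher by 6.18 (SE 0.47, adjusted p = 2.84e-08). Apob, the main apolipoprotein of very low density lipoprotein, was higher by 6.13 (SE 0.37), a 70.1-fold difference. Without ES cell replicate 3 these differences were 7.22 and 6.93. It lay at 11.05 in clone 3.8, 11.19 in clone 6.6, 12.01 in hepatocytes and 4.99 in ES cells. In total 2179 genes were higher and 1489 lower. As against hepatocytes, the SE and p values leave out the spread between the clones.

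All 32 naive pluripotency genes were lower in the clones (camera adjusted p = 4.7e-31, passing with an estimated correlation), with Fbxo15 at -6.57 and Nr0b1 at -6.05. Of 14 primed genes 7 were lower and none higher, with Dnmt3b at -3.34 (camera adjusted p = 0.00804, adjusted p = 0.0895 with an estimated correlation). Of the introduced factors Sox2 (-5.55), Klf4 (-1.58) and Pou5f1 (-1.57) were lower and Myc (1.33) was higher, and the list of 4 did not pass (0.0702). Germ cell genes were lower in 13 of 19, with Mael at -3.06 (1.96e-08), and DNA methylation and Polycomb genes in 13 of 19 with 1 higher, with Tet1 at -5.51 and Jarid2 at -3.69 (7.98e-10). Both passed with an estimated correlation. Cell cycle genes were lower in 23 of 37, with Ccne1 at -2.57 and Bub1 at -2.38 (camera adjusted p = 7.44e-11, adjusted p = 0.336 with an estimated correlation). Most of this came from clone 6.6, where 34 were lower than in ES cells (list mean 7.07 against 9.01), whereas clone 3.8 (8.61) had 6 lower and 1 higher. Glycolysis genes were lower in 6 of 19, with the glucose transporter gene Slc2a3 at -5.01 (camera adjusted p = 0.00027, adjusted p = 0.269 with an estimated correlation). Imprinted genes were lower in 7 and higher in 4 of 26 (0.0518), a list that passed without clone 3.8 replicate 3 (0.0365), clone 6.6 replicate 3 (0.0486) or ES cell replicate 3 (0.0172) and without dim features (0.0419).

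Liver transcription factors were higher in 9 and lower in 1 of 21 (camera adjusted p = 0.000214, adjusted p = 0.163 with an estimated correlation), with the hepatic homeobox gene Hhex at 3.10 (SE 0.12), Onecut2 at 2.45, Onecut1 at 2.45 and Nr5a2 at -2.72. The Onecut2 difference came mostly from clone 6.6. Onecut2 lay at 8.1 to 8.4 there and at 5.1 to 5.4 in clone 3.8, against 4.2 to 4.5 in ES cells. The metabolic liver lists did not pass. Plasma protein genes gave 7 higher and none lower of 39 (0.292), with the retinol carrier gene Rbp4 at 3.87 beside Apob. Higher and lower counts were 1 and 2 of 29 for the urea cycle (0.127), 3 and 0 of 32 for drug metabolism (0.725), 3 and 2 of 21 for gluconeogenesis (0.305) and 6 and 0 of 17 for acute phase genes (0.107). The balance for gluconeogenesis turned when 1 array was left out, to 1 and 3 without ES cell replicate 3 and to 2 and 3 without clone 6.6 replicate 1, and drug metabolism had 1 lower when either of these arrays was left out. Cholangiocyte genes were higher in 7 and lower in 2 of 14, with Bicc1 at 5.50, Anxa13 at 5.33 and Epcam at -4.18 (camera adjusted p = 0.0139, adjusted p = 0.109 with an estimated correlation). Endoderm genes were higher in 8 and lower in 1 of 22, with Gata6 at 3.59 and Lama1 at -3.38 (camera adjusted p = 0.0266, adjusted p = 0.11 with an estimated correlation). ES cell replicate 3 had the highest Apob and Bicc1 values of its group.

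Mesenchymal transition regulators were higher in 13 and lower in 1 of 21, with the N-cadherin gene Cdh2 at 4.80, Axl at 4.38 and Ccn1 at 4.35 (camera adjusted p = 1.08e-05, adjusted p = 0.255 with an estimated correlation). Immediate early and dissociation stress genes were higher in 10 and lower in 2 of 20, with Jun at 2.38, Junb at 2.30 and Nr4a1 at -1.46 (camera adjusted p = 0.000309, adjusted p = 0.267 with an estimated correlation). The epithelial junction and keratin list had 5 of 26 higher, with the simple epithelial keratin genes Krt18 at 4.28 and Krt8 at 3.80, and 10 lower, with Epcam (camera adjusted p = 0.0398, adjusted p = 0.267 with an estimated correlation). It missed the threshold without clone 6.6 replicate 1 (0.06), after centring on reference genes (0.12) and without dim features (0.0771). The p53 and senescence list had 4 higher and 1 lower of 15, with Gadd45g at 2.96 (camera adjusted p = 0.0303, adjusted p = 0.421 with an estimated correlation). It missed the threshold without ES cell replicate 3 (0.069), after renormalization by quantiles (0.0752) and without dim features (0.144). Mesenchymal stem cell surface markers gave 7 higher, with Nt5e at 3.08 and Cd44 at 4.14, and 2 lower of 17 (0.0715), and passed without ES cell replicate 1 (0.0488) or after centring on reference genes (0.0493).

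The other lists did not pass against ES cells. Fibroblast and feeder cell markers gave 8 higher and 3 lower of 30 (0.212), with Fbln2 at 4.66 and Thy1 at -2.19. Oxidative phosphorylation (0.1) passed without ES cell replicate 3 (0.0457), after renormalization by quantiles (0.0102) and after centring on reference genes (0.0442), with 1 of 30 called lower. The mean, median and test differed in sign for the drug metabolism, hepatoblast, stellate cell and reference lists. Xist was higher than in ES cells by 4.73 (SE 0.32), and Eif2s3y and Uty fell by 4.48 and 2.64, whereas Kdm5d was low in ES cells as well as in the clones. Of 36 lists, 13 passed camera, 3 with an estimated correlation and 29 by fry. Centring on reference genes moved the median difference of all genes from -0.027 to -0.159 and the share of calls that were higher from 59.4% to 50.6%, and centring on medians gave 0.086 and 66.6%.

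Genes that differed from both references in the same direction were counted by the calls of both comparisons. There were 1011 higher and 225 lower in the clones. Calls as many in independent lists over all 22180 genes would overlap in 237 and 120 genes. Only 10622 to 10958 genes per array lay above the receptor percentile. Genes under it in every group are less likely to be called, which can make these and the other independent-list values below too low. In 20 simulations without any effect the overlap was 0 and 0, which follows from the few calls made there and gives no measure of what shared arrays add. Because the clone arrays are shared by both comparisons, the overlap was also computed with separate clones. Clone 3.8 against hepatocytes with clone 6.6 against ES cells gave 874 higher and 222 lower, where independent lists would give 273 and 146. The reverse pairing gave 899 and 224, where independent lists would give 233 and 119. Among the fixed lists, members higher than in both references made up 9 of 21 mesenchymal transition regulators (Axl, Ccn1, Ccn2, Cnn1, Itgav, Tgfb1, Tgfb2, Thbs1 and Vim) and 7 of 14 cholangiocyte genes (Anxa13, Bicc1, Krt19, Pkhd1, Slc4a2, Sox9 and Tm4sf4). They were 6 of 30 fibroblast markers (Col12a1, Col6a1, Col6a2, Fbln2, S100a4 and Sparc), 5 of 17 mesenchymal stem cell markers (Cd44, Itgb1, Lepr, Nt5e and Vcam1), 5 of 16 hepatoblast genes (Cd24a, Igf2, Krt19, Sox9 and Tnfrsf12a) and 5 of 22 endoderm genes (Col4a1, Col4a2, Dab2, Gata6 and Sparc). Such a member can rest on 1 clone. Cnn1 lay at 8.5 to 9.2 in clone 3.8 but at 5.0 to 5.5 in clone 6.6, against 5.5 to 5.8 in ES cells. Dab2 lay at 7.3 to 8.7 in clone 6.6 but at 5.7 to 6.0 in clone 3.8, against 5.7 to 6.1 in hepatocytes.

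The comparison of clone 6.6 with clone 3.8 asked how alike the clones were. Efemp1, an extracellular matrix protein, was higher in clone 6.6 by 6.05 log2 units (SE 0.19, n = 3 and 3 arrays, limma adjusted p = 8.02e-11), a 66.2-fold difference. Saa3, an acute phase serum amyloid, was higher by 5.70 (SE 0.33), the matrix proteoglycan gene Dcn by 4.97 (SE 0.32), the uroplakin gene Upk1b by 4.94 (SE 0.31) and Osmr, the oncostatin M receptor, by 4.59 (SE 0.20). Tm4sf1 fell by 4.65 (SE 0.18, adjusted p = 5.99e-10), the calcium-binding protein gene S100g fell by 4.17 (SE 0.27) and Cnn1, a smooth muscle calponin, fell by 3.69 (SE 0.21). Sox2 fell by 3.39 (SE 0.25, adjusted p = 2.61e-07). Of 22180 genes, 402 were higher and 691 lower in clone 6.6, and without clone 6.6 replicate 1 the counts were 500 and 513.

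Cell cycle genes were lower in clone 6.6 in 34 of 37 cases, and none was higher, with Cdc6 at -2.37, Top2a at -1.99 and Mcm5 at -1.94 (camera adjusted p = 4.45e-33, adjusted p = 0.109 with an estimated correlation). Without clone 6.6 replicate 1, 30 were called lower. Oxidative phosphorylation passed as lower (camera adjusted p = 3.93e-05, adjusted p = 0.379 with an estimated correlation) with no member called, the largest differences being Uqcrc1 at -0.67 and Ndufa10 at -0.65. The DNA methylation and Polycomb list had 3 of 19 lower, with the maintenance methylation gene Uhrf1 at -1.77 (camera adjusted p = 0.00557, adjusted p = 0.224 with an estimated correlation, and 0.0712 without dim features), and 1 lower without clone 6.6 replicate 1.

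Interferon response genes rose in clone 6.6 as a list (camera adjusted p = 1.95e-06), the only list of this comparison that also passed with an estimated correlation (0.0145). Of 25 members 3 were called higher, with Ifit2 at 2.74 (SE 0.18). The calls of the others, Bst2 and H2-K1, both ended without clone 3.8 replicate 2 (0.83 and 0.86). That of H2-K1 also ended without clone 3.8 replicate 3 or clone 6.6 replicate 2 or 3. Acute phase genes were higher in 4 of 17, with Lbp at 2.19 and Lcn2 at 1.99 beside Saa3 (camera adjusted p = 0.00198, adjusted p = 0.101 with an estimated correlation). Plasma protein genes were higher in 5 of 39, with Fgb at 1.47 and Hpx at 1.78, or 2.39 without clone 6.6 replicate 1 (camera adjusted p = 0.00557, adjusted p = 0.295 with an estimated correlation, and 0.0752 after renormalization by quantiles). Drug metabolism genes were higher in 2 of 32, with Cyp3a13 at 1.24 (camera adjusted p = 0.014, adjusted p = 0.298 with an estimated correlation), a call lost without clone 6.6 replicate 1 (0.158) and after renormalization by quantiles (0.0863). The gene call of Acox2, the other member, ended without clone 3.8 replicate 2 (0.89) or 3 (0.96). Fibroblast and feeder cell markers were higher in 2 of 30, Dcn and Fstl1 at 1.43 (camera adjusted p = 0.0205, adjusted p = 0.224 with an estimated correlation), a call lost without clone 3.8 replicate 2 (0.0604).

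The immediate early list had 7 of 20 higher, with Egr1 at 1.86, or 2.46 without clone 3.8 replicate 1 (camera adjusted p = 0.0256, adjusted p = 0.45 with an estimated correlation), and lost its call without clone 3.8 replicate 2 (0.0665), clone 6.6 replicate 2 (0.0614) or clone 6.6 replicate 3 (0.0945). The introduced factors passed with 1 of 4 lower, Sox2 (camera adjusted p = 0.0398, adjusted p = 0.269 with an estimated correlation), a call lost without clone 3.8 replicate 2 (0.0557) or clone 6.6 replicate 1 (0.0809), after renormalization by quantiles (0.0752) and without dim features (0.14). The other lists did not pass. Among them, liver transcription factors gave 2 higher, Onecut2 at 3.00 and Prox1 at 1.89, and 2 lower (0.97, with 1 lower without clone 6.6 replicate 1), and mesenchymal stem cell surface markers gave 4 higher, with Mcam at 2.10, and 1 lower (0.148, and 0.0472 without clone 3.8 replicate 3). The stellate cell list (0.0605) passed without clone 3.8 replicate 3 (0.00916), clone 6.6 replicate 2 (0.0429) or ES cell replicate 3 (0.0439) and without dim features (0.0477). The mean, median and test differed in sign for the naive pluripotency, liver transcription factor, cholangiocyte, epithelial, tissue stem cell, trophoblast and germ cell lists.

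Of 36 lists, 10 passed camera between the clones, 1 with an estimated correlation and 16 by fry. Without clone 6.6 replicate 1 there were 1013 calls, of which 875 were among the 1093 with all arrays and in the same direction. Centring on reference genes moved the median difference of all genes from 0.026 to 0.157 and the share of calls that were higher from 36.8% to 51.5%, and centring on medians gave 26.6%.

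Each clone was also set against each reference. Clone 3.8 had 2790 genes higher and 1816 lower than hepatocytes, and clone 6.6 had 2225 and 1896. Against ES cells the counts were 2318 and 1390 for clone 3.8 and 2170 and 1785 for clone 6.6. Centring on reference genes moved the median difference of all genes from -0.072 to -0.574, from -0.016 to -0.387 and from -0.041 to -0.238 for clone 3.8 and clone 6.6 against hepatocytes and clone 3.8 against ES cells, and the share of higher calls from 60.6% to 29.1%, from 54% to 32.3% and from 62.5% to 48.9%. Centring on medians moved the clone 3.8 against ES cell values to 0.128 and 72.8%. Dcn showed the clones moving apart, at 3.07 in clone 3.8, 8.04 in clone 6.6 and 7.13 in hepatocytes, so its call in the clone mean against hepatocytes (-1.57) rests on clone 3.8.

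The position of each clone between the references was read from mean log2 values over list members. The naive pluripotency mean was 4.86 (SD 0.03) in clone 3.8 and 4.80 (SD 0.05) in clone 6.6, against 4.64 (SD 0.06) in hepatocytes and 8.58 (SD 0.08) in ES cells. The small difference from hepatocytes turned negative in clone 3.8 and clone 6.6 with the median over members (-0.092 and -0.081) and after centring on reference genes (-0.28 and -0.21). For the urea cycle, drug metabolism and gluconeogenesis lists the clone means were 4.68 and 4.81, 3.95 and 4.16, and 5.85 and 5.89, near the ES cell means of 4.94, 3.92 and 6.12 and far under the hepatocyte means of 9.67, 9.82 and 10.29. For gluconeogenesis the clone minus ES cell difference turned positive when each array was summarized by its median member (0.28 and 0.077), whereas the median of the members' differences stayed negative (-0.22 and -0.19). Liver transcription factors lay at 5.72 and 5.76 in the clones, above 4.88 in ES cells and under 8.15 in hepatocytes. An exact permutation test of 3 against 3 arrays cannot give a two-sided p under 0.1, and it gave that value for every clone against each reference in these lists, except for drug metabolism in clone 3.8 against ES cells (p = 0.7).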

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

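The tests of Y chromosome loss, swapped arrays, feeder fibroblasts, normalization and clone 6.6 replicate 1 were chosen after the results they concern had been seen, and the others before.

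Clone-specific effects were singled out where the clones differed from each other, and hence in their difference from either reference, by the limma test of clone 6.6 against clone 3.8 (3 and 3 arrays). Among genes named for a comparison with a reference, higher values in clone 6.6 were found for Dcn at 4.97, Onecut2 at 3.00, AW112010 at 2.99, Scd1 at 2.95, Vcam1 at 2.73, Fah at 2.53, Lbp at 2.19, Aldh1a1 at 1.93, Hp at 1.78, Anxa13 at 1.75, Tfcp2l1 at 1.69, Cybb at 1.56, Jun at 1.34, Gata6 at 1.31, Sox9 at 1.27, Cyp3a13 at 1.24, Cpe at 1.15, Nt5e at 1.08 and Acox2 at 1.03. Lower values were found for Sox2 at -3.39, Top2a at -1.99, Mcm5 at -1.94, Bmp4 at -1.80, Uhrf1 at -1.77, Foxa1 at -1.75, Bub1 at -1.74, Mki67 at -1.69, Kif11 at -1.62, Gadd45g at -1.53, Tdrkh at -1.46, Krt19 at -1.41, Ncam1 at -1.21, Dnmt1 at -1.20, Ccne1 at -1.12, Lepr at -1.12, Cebpa at -1.04 and Ocln at -1.02. A few of these calls ended when 1 array was left out, that of Acox2 without clone 3.8 replicate 2 (0.89) or 3 (0.96), of Cebpa without clone 3.8 replicate 1 (-0.67), clone 6.6 replicate 1 (-0.95) or 3 (-0.98), and of Dnmt1 without clone 6.6 replicate 1 (-0.97). The call of Lepr ended without clone 3.8 replicate 3 (adjusted p = 0.0527 by limma) or clone 6.6 replicate 2 (-0.99), and that of Ocln without clone 3.8 replicate 1 (-0.92) or clone 6.6 replicate 2 (-0.83).

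By camera, 10 lists differed between the clones. The mean log2 difference was -1.54 for cell cycle, -1.04 for introduced factors, -0.41 for DNA methylation and Polycomb, -0.31 for oxidative phosphorylation, 0.78 for acute phase, 0.53 for interferon response, 0.51 for immediate early, 0.36 for fibroblast and feeder cell, 0.29 for plasma protein and 0.21 for drug metabolism genes. Only the interferon list also passed with an estimated correlation.

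Outside the genes compared, 1081 of the 12439 features without a single symbol were higher and 679 lower in the clones than in hepatocytes by the same test. These features were not named here.

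In the first pattern weighed, that of the sex-linked genes, Xist lay between 11.18 and 11.79 on clone arrays and between 5.82 and 7.56 on the others, and the Y-linked mean between 3.42 and 3.74 on clone arrays and between 5.78 and 7.41 on the others. The tables argue against loss of the Y chromosome alone, since Xist was higher than in hepatocytes by 5.08, and against arrays swapped between groups, since 0 arrays were closest to one of another group. Female origin of the clones and male origin of the references may account for the pattern, and it predicted that X-linked genes escaping inactivation would be higher in the clones. Their mean difference was 0.71 (SE 0.10) against hepatocytes and 0.10 (SE 0.05) against ES cells, the latter from Kdm6a alone (0.48, adjusted p = 0.00233 by limma), with Kdm5c at -0.04 and Ddx3x at -0.16. The 12 widely expressed reference genes were higher in the clones as well. Their means were 9.65 in clone 3.8, 9.52 in clone 6.6, 9.15 in hepatocytes and 9.45 in ES cells. The escape genes were not tested after centring on them, so scaling could account for the small difference from ES cells. The support that the escape genes add to the Xist and Y-linked values for female origin is thin. It rests on 3 of the 4 genes the test named, since Eif2s3x was not analysed here. Xist and the Y-linked mean divided the clones from both references, so an effect of sex cannot be told apart from other differences between them. The sex of the animals stays open, untested by any record of it.

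Mesenchymal transition genes, higher in the clones than in hepatocytes, were the second pattern weighed. Feeder fibroblasts in the clone samples would bring their collagens, and the mean of Col1a1, Col1a2 and Col3a1 differed from hepatocytes by -0.18, with -0.31 (SE 0.05) in clone 3.8 and -0.05 (SE 0.12) in clone 6.6. These means lay between 4.68 and 4.99 in every group, under the receptor 95th percentile of 5.01. No group thus shows these probes responding. Of 30 fibroblast markers, only Thy1 and Mmp2 were low in hepatocytes and clearly measured in ES cells, at 6.97 and 6.04. Their mean differed from hepatocytes by -0.16 (SE 0.12) in clone 3.8 and -0.15 (SE 0.12) in clone 6.6. These 2 markers argue against feeder cells as the whole source, but that choice left out markers low in ES cells. Of the 30, 6 were higher than in both references (Col12a1, Col6a1, Col6a2, Fbln2, S100a4 and Sparc), so a share of feeder cells stays open. Normalization is argued against by a list mean that was still 0.88 under the scaling that lowered it most. A growth state of the cultures and an outgrowth of a liver cell other than the hepatocyte stay open as untested explanations.

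The lower cell cycle values in clone 6.6 (list mean -1.54) were not matched by any of 10000 random lists of like expression, 0 of which shifted as far (lowest -0.52), and 30 members were called lower without clone 6.6 replicate 1, a count exactly at the bound set for that test. Such random lists leave out that cell cycle genes move together, and with an estimated correlation the list missed the threshold (camera adjusted p = 0.109).

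Other splits of the same arrays were counted for each comparison by fits of the groups compared, and in each of the 8 only 1 split, the real one, gave as many genes. For both clones against hepatocytes the real split was 1 of 84, a share under 0.05. It gave 4062 genes against 712 in the highest other split, which set the clone 3.8 arrays apart. For both clones against ES cells it was also 1 of 84, with 3494 against 805 in a split that set the clone 6.6 arrays apart. These highest splits follow the clones, so arrays of a clone are not exchangeable with those of the other. A share of splits needs exchangeable arrays, so chance is not excluded here, for arrays or for the 2 clones as units. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. There the real values were 5099 for ES cells against hepatocytes, 1064 for clone 6.6 against clone 3.8, 4607 and 4116 for clone 3.8 and clone 6.6 against hepatocytes, and 3712 and 3948 against ES cells, and the highest other value was 0 each time.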

How the results depend on the processing

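The counts without hepatocyte replicate 1, ES cell replicate 3 and clone 6.6 replicate 1 within lists were chosen after seeing the data, and the other alternatives before. Under repeated quantile normalization, median or reference centring, array weights, trended or robust priors, the mean of features and fits of only the groups compared, each total of called genes stayed within 1.5 times its value, as it did without dim features. The split by direction did not after reference centring, with 1372 higher and 2995 lower for both clones, 1488 and 3617 for clone 3.8 and 1366 and 2868 for clone 6.6 against hepatocytes. No named gene reversed, and no list test reversed in the direction camera gives relative to other genes, though the glycolysis mean for both clones against hepatocytes turned from 0.41 to -0.02 after reference centring. Of 144 list tests, the side of the threshold changed in 37 with an estimated correlation, 43 with fry, 10 after reference centring and 7 after quantile normalization, and without dim features in 13 of the 136 that could be run. Of 456 values of named genes, 21 changed sides after reference centring and 6 after median centring. Genes near the receptor level (95th percentile 5.01) limit what a fall can show.

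In the order ES cells, both clones, clone 3.8 and clone 6.6 against hepatocytes, both clones, clone 3.8 and clone 6.6 against ES cells, and clone 6.6 against clone 3.8, no minimum difference gave 10112, 10062, 9556, 8782, 9134, 8462, 8280 and 3569 calls, a minimum log2 difference of 2 gave 2068, 1598, 1812, 1565, 1111, 1132, 1296 and 185, and treat gave 3147, 2581, 2698, 2362, 1965, 1780, 2097 and 228, as looser or stricter criteria must. All features gave 7904, 5734 and 5866 calls for ES cells against hepatocytes and for both clones and clone 3.8 against ES cells, with more features tested, and raised the higher calls of both clones and clone 6.6 against hepatocytes to 3652 and 3474 and the lower calls of clone 6.6 against ES cells to 2834. Leaving out 1 array gave 5083 to 5149, 4146 to 4342, 4461 to 4714, 4065 to 4314, 3615 to 3843, 3629 to 3877, 3877 to 4205 and 1013 to 1255. Lists past the threshold ranged from 20 to 21 for ES cells and 15 to 17 for both clones against hepatocytes, 12 to 14 for both clones against ES cells and 7 to 12 between the clones. They numbered 10, 8, 3 and 1 with an estimated correlation, and 29, 29 and 16 by fry in the last 3 of these. Of 288 list counts, 37 changed without hepatocyte replicate 1, 31 without ES cell replicate 3 and 54 without clone 6.6 replicate 1, by at most 2, 2 and 4 members.

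The correlation of clone arrays with the ES cell and hepatocyte means was 0.758 and 0.596 without dim features and 0.902 and 0.865 by Spearman. List values per array are given as the median over members, then after reference centring. Naive pluripotency turned negative against hepatocytes in clone 3.8 (-0.092, -0.28) and clone 6.6 (-0.081, -0.206) and was -4.121, -3.913 and -4.11, -3.84 against ES cells. Plasma proteins gave -7.116, -7.126 and -7.04, -6.702 against hepatocytes and 0.015, 0.17 and 0.092, 0.594 against ES cells. The urea cycle list gave -5.496, -5.497 and -5.496, -5.233 against hepatocytes and, in clone 3.8, -0.06, -0.454 against ES cells. Drug metabolism gave -6.432, -6.372 and -6.104, -6.03 against hepatocytes, -0.259, -0.171 in clone 3.8 and, by median, 0.069 in clone 6.6 against ES cells. Gluconeogenesis gave -4.945 (clone 3.8, centred) and -4.759, -4.766 against hepatocytes, and against ES cells 0.279, -0.475 and 0.077, -0.297, with the medians reversed. Liver transcription factors gave -2.722, -2.936 and -2.696, -2.758 against hepatocytes, and 0.636 (clone 3.8, centred) and 0.941, 0.814 against ES cells. The cause was not tested.

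Arrays of the same number were not paired, since only 2 of 18 pairs had an r over 0.1 (range -0.31 to 0.17) and 4 fitted best with their own number. With the number as a block the counts, in the order above, were 5098, 4200, 4605, 4121, 3667, 3707, 3956 and 1088, and no list test or named gene changed sides.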

Other observations

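The lists of Hippo pathway targets and intestinal genes and the tests of clone RNA on single arrays were chosen after related genes had been seen, and the bound of each test was written before its result.

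YAP and TEAD activity in the clones was a hypothesis formed from Ankrd1, Myof, Ccn1, Ccn2 and Axl among the genes high in both clones. It predicted that 14 further target genes, whose values had not been looked at, would be higher. Their mean difference was 1.91 against hepatocytes and 1.94 against ES cells, with 11 of 14 higher and 0 lower in each comparison (camera adjusted p = 4.42e-07 and 1.29e-07, and adjusted p = 0.061 and 0.061 with an estimated correlation, which misses the threshold). The members higher in both were Amotl2, Lats2, Asap1, F3, Crim1, Fjx1, Foxf2, Ccdc80, Ptpn14, Arhgef17 and Nuak2. The direction is in line with the prediction, but the call rests on the preset correlation, and adherent growth, which could raise the same targets, was not tested.

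An intestinal character of clone 6.6 was a hypothesis formed from Reg1, Reg3b and Cdh17, which were higher in that clone. Of 11 further intestinal epithelial genes 0 were higher and 1, Krt20, was lower in clone 6.6 than in clone 3.8 (mean -0.05, camera adjusted p = 0.409, and adjusted p = 0.605 with an estimated correlation). The prediction was not met.

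RNA of the clones on hepatocyte replicate 1 and ES cell replicate 3 was a hypothesis formed from Bicc1, Krt19 and Xist and the third pattern weighed. It predicted that at least 90% of further genes high in both clones would be highest on each of these arrays, and the shares were 93.5% (43 of 46) on hepatocyte replicate 1 and 63% (29 of 46) on ES cell replicate 3, where chance gives 33.3%. Genes high in the other reference cell type were highest there in at most 38.7% of cases. This argues against a wider spread or the normalization of these arrays. On hepatocyte replicate 1, genes high in clone 3.8 only were highest in 83.3% (10 of 12) and genes high in clone 6.6 only in 33.3% (5 of 15). That argues against a change of the cells themselves toward a state common to both clones, though these genes are few and not independent. It cannot tell RNA of clone 3.8 from a change of the cells toward clone 3.8 alone. A small amount of clone 3.8 RNA, at a median of 3.02% of the clone level over genes high in clone 3.8 only and 4.33% over genes high in both, is a candidate explanation on hepatocyte replicate 1, and on ES cell replicate 3 the share lay between the bounds of 60% and 90% and left it undecided. In a simulated mixture of 5% clone 6.6 RNA on hepatocyte replicate 2, 59% (23 of 39) of such genes were highest there, under the lower bound. Hepatocyte replicate 1, itself high for such genes, stayed in that comparison and could outrank the mixture. Where another array of the group is high, a share under these bounds cannot exclude clone RNA. How the bounds perform in a group without such an array, as for ES cell replicate 3, was not simulated.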
